A study of Mus musculus with 4 samples.

How the data were processed

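The samples were 2 primary prostate tumours and 2 bone metastases of 2 NPK mice, dissociated with enzymes and loaded at 10000 cells per sample with over 70% viability for droplet capture of single cells. The submitters' processing notes name Cell Ranger 2.0.0, DESeq2 and the mm9 genome build, with no role or order for each. How values were normalized, how genes without reads were given values and whether libraries were integrated is not given in the sources used here. The deposited table of mouse 1 was taken to hold log2 values. This rests on 3 of 5141 cells, all tagged CJ002, in which values fell on steps: the second step lay within 0.016 (median) of log2(1 + 2s) for a first step log2(1 + s), and 0.242 from the natural logarithm. The deposited table of mouse 2 holds a score, log-like by its shape, in which no cell had such steps, so that its base is not shown. In both tables every gene has a continuous value in every cell, none is exactly 0, and 56.1% and 56.7% of values are below 0. Values ranged from -7.27 to 15.7 in mouse 1 and from -11.3 to 13.5 in mouse 2. No mitochondrial genes are among the 23285 genes, and gene symbols follow an older nomenclature, with EYFP as a gene of its own.

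Because the values are not counts, the planned filters on detected genes and mitochondrial share could not be applied, and all cells were kept. The depth per cell is unknown. Exact (Clopper-Pearson) 95% intervals were given for shares of cells, and cover counting of cells only. Doublets could not be called without counts. In an alternative, cells past the midpoint for markers of another class were left out. This took out 1509 cells (29.35%) of mouse 1 and 2615 cells (29.95%) of mouse 2, of which 494 and 1386 were keratin-positive. It kept 678 of the 1492 neutrophil-lineage-like cells of mouse 1. The cells left out are possible doublets only, and the alternative is not a doublet call.

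Each table was analysed alone. Unexpressed genes scatter around a common value below 0, and this background was estimated from the 3000 genes of lowest mean, giving a mean of -0.483 (SD 1.18) in mouse 1 and -1.81 (SD 1.70) in mouse 2. A level is a mean over cells minus this background. In mouse 2, 5565 genes formed a separate narrow band (mean 0.604, SD 0.526 over cells) with no variation to speak of, and were left out, which left 17720 genes for that mouse. The 2000 most variable genes were reduced to 30 principal components, a graph of 15 neighbours was built, and cells were grouped by the Leiden method at resolution 1.0 with a fixed seed, giving 16 clusters in mouse 1 and 29 in mouse 2.

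Clusters were named from marker lists written before the data were seen. A cluster was named only where its leading gene was at least 2 units above the mean of the other clusters. It was keratin-positive where at least 2 of Krt8, Krt18 and Krt19 had a level of 2 or more, and Epcam-positive where Epcam did so as well. Other clusters took the name of the list leading their 10 top genes, with at least 3 markers at a level and a lead of 1 or more, and the rest stayed unnamed. Markers of neutrophils and of their precursors were joined as the neutrophil lineage. Names end in "-like" since they rest on markers alone. The keratin and Epcam rules, their thresholds, the lead of 2, which left a cluster of 431 cells in mouse 2 unnamed, and the tie-break by share of a list detected were set after the data were seen. Clusters 1 and 7 of mouse 1 (1240 cells) and 3, 5, 16 and 26 of mouse 2 (1712 cells) kept the keratin-positive name. None of their 10 top genes was luminal, while 1 or 2 belonged to another list, and they are called led by another list below. In mouse 1 these genes were Col1a2 in cluster 1 and Col1a2 and Col3a1 in cluster 7 (fibroblast list). In mouse 2 it was Vcan alone in clusters 3, 5 and 16 (monocyte list) and Sox9 alone in cluster 26 (chondrocyte list). These 4 clusters had 3, 3, 4 and 3 fibroblast markers at a level and a lead of 1 or more, against 2, 0, 2 and 1 luminal markers. Cluster 7 of mouse 1 had 5 fibroblast markers and 0 luminal markers by that count, and would have been fibroblast-like without the keratin rule. The background scale, the exclusion of the narrow band, the use of the mean of deposited values (planned as an alternative to the log2 of the mean) and the limits below were also set after the data were seen.

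Column tags match no sample label. Following the plan for that case, no fit of bone metastasis against primary tumour was made, and the limma, edgeR and camera tests planned for it were not run. For each class found in both mice the difference of its level from the mean of the 4 other such classes, weighted equally, was taken for every gene. The 22 fixed gene lists, of which 1 member was not found, were summarised by the median difference of their members and its percentile among 10000 random lists matched in 50 bins of mean expression. A list was called where the percentile was below 2.5 or above 97.5 on the same side in both mice. A percentile compares genes within 1 table, with cells of 2 libraries pooled, and is not a test over animals. Members were counted as higher or lower at a difference of 1 unit. Neutrophil markers share genes with the neutrophil maturation list, and the keratins that define a class are members of the epithelial list. The macrophage alternative list shares C1qa and Mrc1 with the macrophage markers and Chi3l3 with the monocyte markers.

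The genes named in the text followed a rule written before the data were seen. For each class they are the 10 genes with the largest difference from the other classes, ranked by the smaller of the differences in the 2 mice, with a level of at least 2 in place of the planned expression threshold, leaving out ribosomal, haemoglobin, immunoglobulin, Rik and Gm-number genes. From each list the 3 members of highest level could be named, and Nkx3-1, Pten, Kras, Myc and Ar. For keratin-positive cells the 10 largest rank differences in each direction between the tables, among genes with a level of at least 2 in either, were added, in place of the planned log2 differences. The genes set side by side between libraries and between clusters, EYFP, the keratins and Epcam were chosen after the data were seen.

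The procedure was tested on simulated data. Values were drawn with each gene's mean and within-class SD, and shifts of 0.5, 1.0 and 2.0 up or down were put into random genes of the keratin-positive cells. Clustering and naming were not part of it. With these shifts the sign was recovered for all 67, 67 and 66 genes in each mouse, with median absolute errors of 0.032 to 0.041 in mouse 1 and 0.071 to 0.083 in mouse 2. Of 100 lists of random genes with no shift, 6 in mouse 1 and 2 in mouse 2 fell outside the limits. Genes were drawn independently of each other, and no other class or library differences were put in. The simulation therefore gives no rate of false calls for lists of genes that vary together.

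The tests of technical sources were set after the results were seen. For collagen, a first form of the doublet test on cells chosen by their Col1a2 level was dropped, since that choice widens the gap it measures, and all keratin-positive cells were used with the same bounds. Bgn was added to Dcn after its level was known.

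Alternatives were Leiden resolutions of 0.5 and 2.0, possible doublets left out, 10 principal components, the median over cells, the log2 of the mean over cells (mouse 1), keratin-positive clusters led by another list left out, and each library alone. A list median or a gene level counted as moved at 0.5 units or more, and a share as moved outside its interval. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.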

Results

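Single-cell RNA sequencing was done on anterior lobe prostate tumours and dissected bone metastases of 2 mice of the NPK model. In this model a tamoxifen-activated Cre recombinase driven from the Nkx3-1 locus deletes Pten, a brake on PI3K signalling, and switches on an activated Kras allele. A yellow fluorescent protein gene (EYFP) switched on by the same Cre marks recombined cells and their descendants. Tamoxifen was dosed at 100 mg/kg for 4 days when the males were 2 to 3 months old. Mouse 1 was sampled at 6 months of age, and its bone sample held 2 vertebral lesions and 1 femoral lesion. Mouse 2 was sampled at 8 months of age, and its bone sample held 1 femoral, 1 pelvic and 1 tibial lesion. The labels give 4 samples, 2 primary tumours and 2 bone metastases, matched within each mouse.

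The data form 1 table per mouse, with 23285 genes in 5141 cells for mouse 1 and in 8732 cells for mouse 2. The barcodes of mouse 1 fell into 2 libraries, with 3153 cells carrying no tag and 1988 tagged CJ002. Those of mouse 2 fell into CJ003 with 4203 cells and CJ004 with 4529 cells. No label ties a tag to the tumour or the bone of a mouse, so primary tumour and bone metastasis were not compared. The cell classes of each library and the genes that set them apart are described instead, and the libraries of a mouse are set side by side without a test. The tables hold continuous normalized values and no counts, so the depth per cell is unknown. Expression is given as a level, the mean value over cells minus the mean value of unexpressed genes in the same table. Levels of mouse 1 were taken to be in log2 units, which rests on 3 of 5141 cells, all of CJ002. Levels of mouse 2 are in the deposited score, whose log base is not shown. The tables were normalized separately, so levels were compared only within a mouse. There were no replicate libraries, and every SD is over cells, which are not replicates.

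Cells with keratins and cells of the neutrophil lineage made up most of both tables. Keratin-positive cells, with Krt8, Krt18 and Krt19 (intermediate filament proteins of simple epithelia) as their defining genes, were 94.6% of the untagged library of mouse 1 (2983 of 3153 cells, exact 95% interval 93.8 to 95.4%). In CJ002 of the same mouse they were 12.1% (241 of 1988 cells, 10.7 to 13.6%). In mouse 2 they were 80.7% of CJ003 (3391 cells, 79.5 to 81.9%) and 22.6% of CJ004 (1022 cells, 21.4 to 23.8%). Neutrophil-lineage-like cells, led by the calprotectin genes S100a8 and S100a9, were 73.9% of CJ002 (1470 cells, 72.0 to 75.9%) against 0.698% of the untagged library (22 cells, 0.438 to 1.06%). In mouse 2 they were 51.9% of CJ004 (2352 cells, 50.5 to 53.4%) and 7.64% of CJ003 (321 cells, 6.85 to 8.48%).

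Monocyte-like cells were 10.1% of CJ002 (201 cells) and 11.9% of CJ004 (539 cells), against 1 cell of the untagged library and 21 cells of CJ003. Macrophage-like cells were 3.36% of the untagged library (106 cells), 0.553% of CJ002 (11 cells), 2.05% of CJ003 (86 cells) and 1.30% of CJ004 (59 cells). Fibroblast-like cells were rare, at 38 cells in the untagged library, 1 in CJ002, 25 in CJ003 and 4 in CJ004. This depends on the keratin rule, under which cluster 7 of mouse 1 (314 untagged cells, with 5 fibroblast markers) was counted as keratin-positive. Erythroid-like cells were found in mouse 2 alone, with 106 cells in CJ004 and 19 in CJ003. No cluster took its name from the endothelial, smooth muscle, T cell, NK cell, B cell, plasma cell, osteoblast or osteoclast markers. Trac and Trbc2 (T cell), Ighm and Ighd (B cell), Mzb1 (plasma cell) and Ocstamp (osteoclast) were not found among the genes. These names therefore rested on shorter lists, and a missing name does not show that the cells were absent. Unnamed clusters held 67 cells in mouse 1 and 757 in mouse 2, of which 431 formed a cluster with keratin transcripts but no gene far enough ahead of the other clusters for a name. With possible doublets left out, neutrophil-lineage-like cells were 0.224% of the untagged library and monocyte-like cells 4.73% of CJ004. With coarser clusters (resolution 0.5) monocyte-like cells were 2.02% of CJ003 and mouse 2 had no macrophage-like class, and with 10 principal components macrophage-like cells were 0.999% and 0.707% of CJ003 and CJ004 and neither mouse had a fibroblast-like class.

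**Figure D1:**
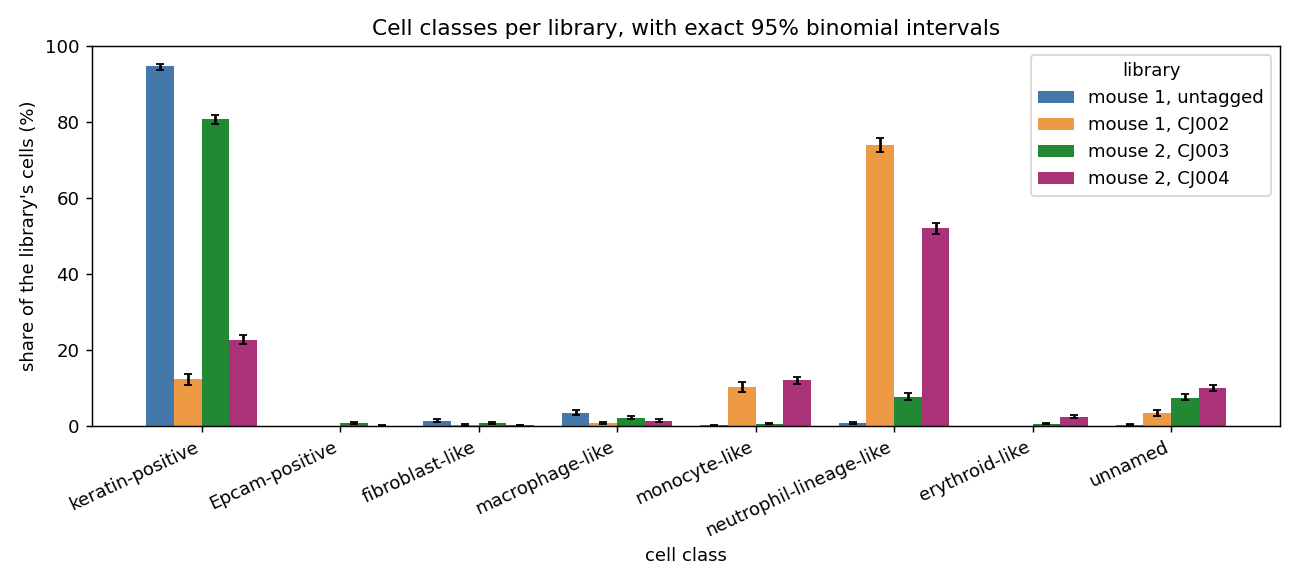
Share of the cells of each library in each class (y axis, percent), with bars coloured by library and exact 95% binomial intervals. Keratin-positive cells took 94.6% and 80.7% of the untagged and CJ003 libraries, and neutrophil-lineage-like cells took 73.9% and 51.9% of CJ002 and CJ004.

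Keratin-positive cells expressed simple epithelial keratins together with Vim and Fn1 in both mice. Over both libraries of a mouse, Krt18 had a level of 4.10 in mouse 1 and 6.90 in mouse 2, which was 3.59 and 6.37 above the mean of the 4 other classes found in both mice. Vim, the intermediate filament of mesenchymal cells, stood at 6.64 and 8.76, and Fn1 (fibronectin) at 4.24 and 6.74, close to its 4.08 and 6.69 in monocyte-like cells. The adhesion genes Epcam and Cdh1 (E-cadherin) were close to background, with Epcam at 0.04 in mouse 1 and 0.118 in mouse 2 and Cdh1 at 0.04 and 0.265. The genes furthest above the other classes in both mice were Ctla2a, an inhibitor of cysteine proteases (by 4.66 and 5.53), Spp1 or osteopontin, a secreted bone matrix phosphoprotein (by 3.61 and 5.41), and Lgals1 or galectin 1 (by 3.60 and 4.36). They were followed after Krt18 by Stmn2, a microtubule regulator (3.13 and 3.74), Rbp1, a cellular retinol carrier (3.11 and 5.48), Mt2, a metallothionein (3.01 and 3.44), and Nupr1, a stress-induced transcription cofactor (2.99 and 5.11). Mgp or matrix Gla protein, an inhibitor of calcification (2.97 and 5.64), and S100a4, a calcium-binding protein of motile cells (2.93 and 4.80), completed the 10 genes.

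Across 17720 genes the difference of keratin-positive cells from the other classes correlated between the mice, with a Pearson r of 0.866 and a Spearman rho of 0.751. For the other classes Pearson r was 0.683 for neutrophil-lineage-like, 0.688 for monocyte-like, 0.724 for macrophage-like and 0.695 for fibroblast-like cells, with Spearman rho at 0.555, 0.377, 0.523 and 0.41. These are correlations across genes, which are not independent replicates, and no p was computed. The libraries of a mouse filled the classes unevenly, so differences between libraries may enter these correlations as well.

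The genes altered in the model and the androgen receptor were read in the same cells. EYFP was at 1.55 in keratin-positive cells of mouse 1 and 2.82 in those of mouse 2, against 0.17 and 0.013 in neutrophil-lineage-like cells and 0.07 and 0.054 in monocyte-like cells. In mouse 1 the gap was smaller within a library, with EYFP at 1.61 in keratin-positive and 1.03 in the 22 neutrophil-lineage-like cells of the untagged library, which also carried Ctla2a at 4.30, and at 0.76 and 0.16 in CJ002. Macrophage-like cells carried EYFP at 0.74 in mouse 1 and 0.153 in mouse 2, and fibroblast-like cells at 0.77 and 0.576. Other transcripts of keratin-positive cells were also found in the untagged macrophage-like cells of mouse 1, with Ctla2a at 3.70 and Spp1 at 3.61, against -0.25 and 1.77 in the 11 of CJ002. Kras was at 1.53 and 3.37 in keratin-positive cells, against 0.65 and 0.952 in the neutrophil lineage and 0.63 and 1.90 in fibroblast-like cells. The activated Kras allele was not told apart from the normal allele. Pten was at 0.92 and 3.19 in keratin-positive cells and at 1.32 and 2.22 in the neutrophil lineage, and the loss of its floxed exons was not read here. Nkx3-1, the luminal homeobox gene, stood at 0.03 in mouse 1 and 0.044 in mouse 2, Ar (androgen receptor) at 0.29 and 0.664, and Myc at 0.47 and 0.715. Among the 17720 genes ranked by level in keratin-positive cells, EYFP lay at percentile 92.2 in mouse 1 and 91.8 in mouse 2, Kras at 92.1 and 94.6, Pten at 84.8 and 93.7, Ar at 63.0 and 61.0, and Nkx3-1 at 19.6 and 29.7.

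**Figure D2:**
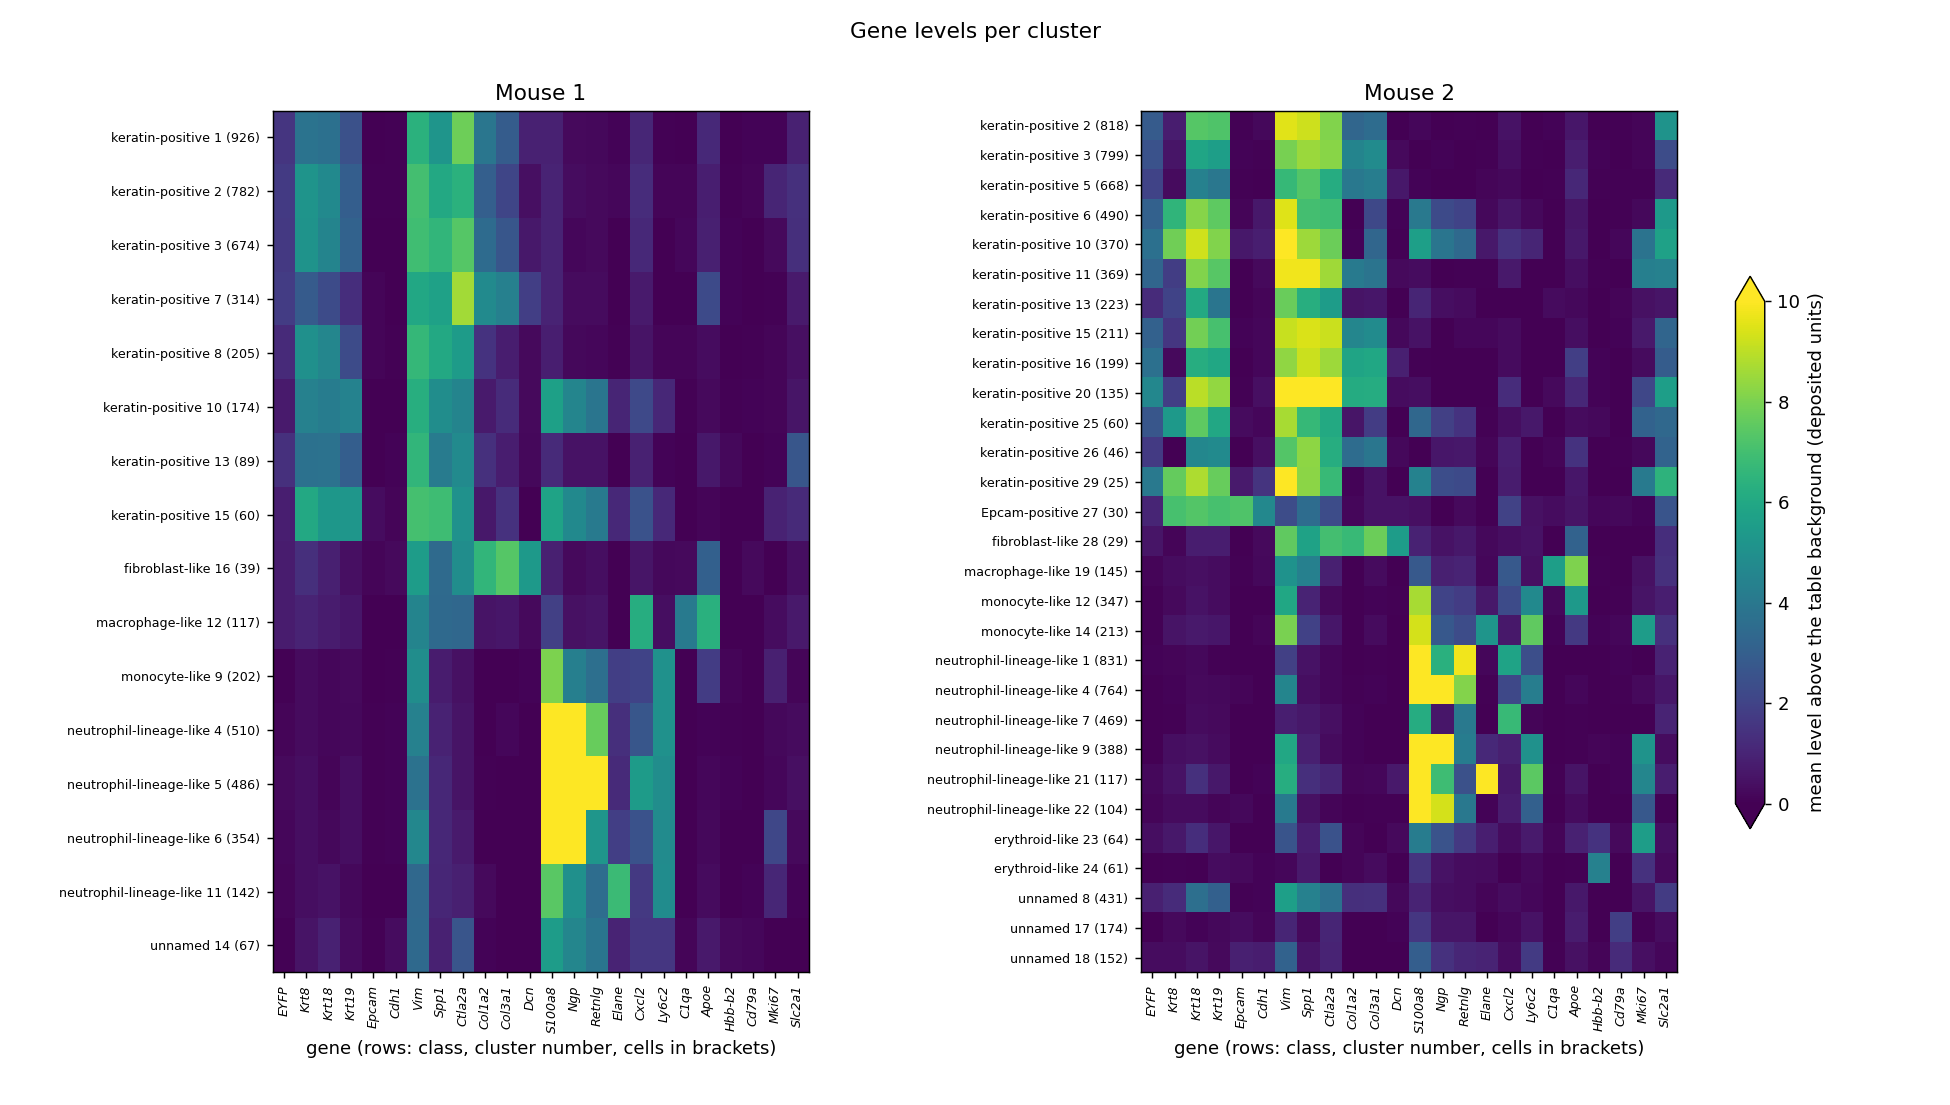
Level of 24 genes (x axis) in each cluster (y axis, with the class, cluster number and cell count), mouse 1 left and mouse 2 right, coloured by mean level above background in deposited units. Keratin-positive clusters carry Krt18, Vim and Spp1, the 30-cell Epcam-positive cluster of mouse 2 has Epcam at 7.25, and S100a8 reaches 12.1 in cluster 4 of mouse 1.

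The glycolysis, RAS/MAPK, MYC-associated and epithelial lists had higher medians than matched random lists in keratin-positive cells, both libraries pooled. Not every member was higher. In mouse 1, 2983 of 3224 keratin-positive cells were untagged, and 1470 of 1492 neutrophil-lineage-like cells were of CJ002. In mouse 2, 3391 of 4413 keratin-positive cells were of CJ003, and 2352 of 2673 neutrophil-lineage-like cells of CJ004. A difference between libraries could therefore enter these contrasts, and single libraries are given below. Of the 22 gene lists fixed in advance, 10 lay outside the central 95% of 10000 expression-matched random lists in both mice when keratin-positive cells were set against the mean of the 4 other classes. The hypoxia and glycolysis list had a median difference of 0.83 in mouse 1 (percentile 99.9) and 2.15 in mouse 2 (above every random list), and 8 and 13 of its 17 genes were higher by at least 1 unit. Keratin-positive cells were higher on most genes, and random lists matched to this one had medians of 0.34 and 1.14. Its most abundant members were Gapdh (1.66 and 2.77 above the other classes), Aldoa (1.01 and 2.19) and, in mouse 1, Ldha (1.28), all enzymes of glycolysis. The list of RAS/MAPK feedback and target genes had medians of 0.53 and 1.18 (percentiles 99.97 and 99.99), against 0.23 and 0.617 for matched random lists. Of its 21 genes 4 and 13 were higher, and 1 was lower in mouse 1. Its most abundant members went both ways, with Phlda1 differing by 0.87 and 2.95, Ier3 by -0.05 and 0.676, and Plaur, the urokinase receptor, by -1.18 and -0.277. The MYC-associated list of ribosome biogenesis and metabolism had medians of 0.55 and 1.19 (percentiles 98.7 and 98.9), against 0.37 and 0.869 for matched random lists. Of its 30 genes 9 and 23 were higher. Npm1 (nucleophosmin) stood at 4.54 and 6.73, Eif4a1, a translation initiation helicase, at 4.05 and 5.66, and Ran, a nuclear transport GTPase, at 3.45 in mouse 1. The epithelial junction and keratin list had medians of 0.18 and 0.592 (percentiles 99.6 and 100), against 0.06 and 0.157 for matched random lists. Of its 14 genes 4 and 5 were higher, and 3 of its genes are the keratins that define the class. Counts of higher members also follow the shift of most genes. In mouse 2 oxidative phosphorylation, inside the limits, had 16 of 17 genes higher.

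Of the other 6 lists, 5 were below the mean of the other classes, which holds the neutrophil and macrophage classes. Apart from MHC class I these lows were shared in both mice with at least 1 other class. For MHC class I other classes were lower in a single mouse. Fibroblast-like cells were at -0.36 in mouse 1 and 0.0061 in mouse 2. Neutrophil-lineage-like cells were at 0.338 in mouse 1 and -0.895 in mouse 2 (percentile 61.2, inside the limits). Fibroblast-like cells had medians of -1.34 and -1.38 for neutrophil maturation and -0.34 and -0.144 for NF-kB, and Cd74 (MHC class II) was at 0.20 and 0.128 in keratin-positive and 0.23 and 0.093 in neutrophil-lineage-like cells, against 4.36 and 4.31 in macrophage-like cells. Neutrophil maturation and activation had medians of -1.42 and -1.55, MHC class II presentation -0.77 and -0.777, and the NF-kB and inflammatory list -0.33 and -0.319, each below every random list in both mice. The macrophage alternative and tumour-associated list had medians of -0.15 and -0.358, also below every random list, although its member Spp1 was 3.61 and 5.41 higher. MHC class I presentation had medians of -0.23 and -0.16 (percentile 0.01 in both), with H2-D1 at 2.55 and 4.46 and B2m, the class I light chain, at 3.57 and 4.40 in keratin-positive cells. The list of luminal progenitor or club-like secretory genes had medians near 0, at -0.02 and -0.0022 (percentiles 1.95 and 1.65), and its members went both ways. Sox9, a progenitor transcription factor, was 2.37 and 4.35 higher, while Lcn2 (lipocalin 2), abundant in neutrophils, was lower with differences of -3.13 and -3.32.

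Lists called in 1 mouse only were unfolded protein and amino acid stress, with a median of -0.04 in mouse 1 (percentile 0.08) and 0.939 in mouse 2 (percentile 40.3), and cell cycle G2 and M phase, at 0.23 (43.1) and 0.21 (0.36). The remaining 10 lists lay inside the limits in both mice. PI3K/AKT/mTOR-associated genes had medians of 0.37 (percentile 95.1) and 0.574 (45.2), mesenchymal transition 0.43 (83.5) and 0.898 (64.9), and oxidative phosphorylation 0.64 (46.7) and 1.50 (37.3). Androgen-regulated and differentiated luminal genes, of which 17 and 15 were measured, were at 0.04 (69.6) and 0.0767 (51.9). Their most abundant member, Fkbp5, was 0.911 and 1.12 higher. Among the 3 most abundant in 1 mouse only, Hoxb13, a prostate homeobox gene, was 1.15 higher in mouse 1. Foxa1, a cofactor of the androgen receptor, was 2.84 higher in mouse 2. The bone matrix and osteotropic list was at 0.16 (94.1) and 0.136 (35.0), cell cycle S phase at 0.21 (28.1) and 0.39 (26.3), and p53 and senescence at 0.27 (80.1) and 0.0936 (7.53). Interferon response was at 0.01 (13.4) and 0.121 (27.6), dissociation and immediate early genes at 0.45 (16.6) and 1.08 (4.95), and T cell activation and exhaustion at -0.0042 (37.5) and 0.0274 (69.4).

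Within single libraries some of these calls ended, and the RAS/MAPK call of mouse 1 held in neither of its libraries. The MYC-associated list was at percentile 88.0 in CJ002 alone and 91.8 in CJ003 alone, RAS/MAPK at 92.5 in the untagged library, 85.4 in CJ002 and 92.7 in CJ003, hypoxia and glycolysis at 84.9 in CJ002 and 92.3 in CJ003, and the epithelial list at 76.3 in the untagged library and 96.6 in CJ003. In CJ004 alone the MYC-associated and RAS/MAPK medians were 2.05 and 2.16 and the MHC class I median turned positive at 0.171, still below random. The luminal progenitor median turned positive in the untagged library, CJ003 and CJ004 alone, and in CJ002 alone it stayed negative but inside the limits. With possible doublets left out, it was positive and inside the limits in both mice (0.05, percentile 17.5, and 0.073, percentile 9.61). It also changed under other settings given below.

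**Figure D3:**
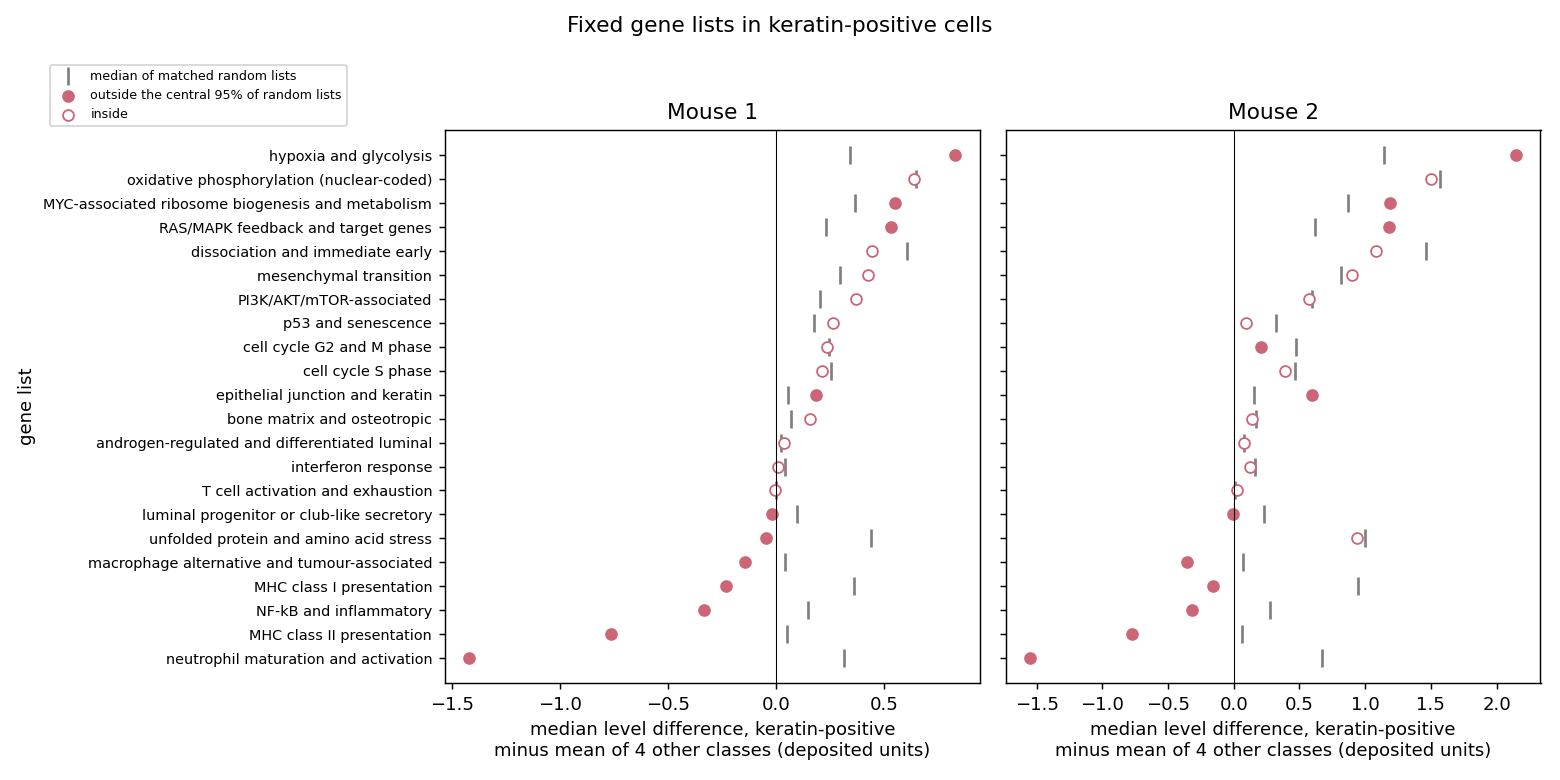
Median level difference of keratin-positive cells from the mean of 4 other classes (x axis, deposited units) for 22 gene lists (y axis), with filled points outside the central 95% of matched random lists and grey ticks at the random median. Hypoxia and glycolysis is furthest right at 0.83 and 2.15, and neutrophil maturation and activation furthest left at -1.42 and -1.55.

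Keratin-positive cells of the 2 libraries of a mouse differed in Col1a2 and Wfdc2 in both mice and in Krt8 in mouse 2. The libraries filled almost separate clusters: apart from cluster 13 of mouse 2 (132 and 91 cells), no keratin-positive cluster held more than 9 cells of its smaller library, so different clusters are compared. Some keratin-positive clusters had no luminal marker among their 10 top genes but 1 or 2 genes of another marker list. Of their cells in mouse 1, where these genes were Col1a2 and Col3a1, 1239 of 1240 were untagged. In mouse 2, where the gene was Vcan or Sox9, 1710 of 1712 were of CJ003. Each of these clusters of mouse 2 also had more fibroblast than luminal markers at a level and a lead of 1 or more. In mouse 2 Krt8 stood at 0.801 (SD 2.29) in the 3391 cells of CJ003 and at 6.80 (SD 2.14) in the 1022 cells of CJ004, while its partner Krt18 was at 6.45 (SD 2.11) and 8.38 (SD 1.28) and Krt19 at 6.01 and 7.33. Wfdc2, a secreted protease inhibitor of glandular epithelium, was at 2.39 and 6.75, Areg, an EGF receptor ligand, at 1.99 and 5.31, and Perp, a desmosome protein, at 0.091 and 3.15. Some matrix genes ran the other way, with Col1a2 (a type I collagen chain) at 4.07 (SD 2.00) in CJ003 and 0.014 (SD 1.74) in CJ004, Col1a1 at 3.05 and 0.138, and Sparcl1, a matricellular protein, at 5.13 and 0.349, whereas Fn1 (6.70 and 6.90) and Sparc (5.39 and 5.14) differed little. Vcan (versican) was at 5.29 and 3.05, and Sulf1, a heparan sulfate editing enzyme, at 3.39 and 0.929. EYFP was at 2.72 (SD 1.73) and 3.13 (SD 1.70).

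In mouse 1 Krt8 was alike in the libraries, at 4.44 (SD 1.31) in 2983 untagged cells and 4.81 (SD 1.46) in 241 cells of CJ002, with Krt18 at 4.06 and 4.49. Krt19 was at 2.64 and 4.62, Krt7 at 0.12 and 1.68, the tight junction gene Cldn3 at 0.52 and 2.23, Wfdc2 at 2.44 and 4.00, and Spint2, a membrane protease inhibitor, at 0.26 and 2.89. Col1a2 was at 3.46 (SD 1.28) in untagged and 0.65 (SD 1.23) in CJ002 cells, Col3a1 at 2.58 and 1.24, and Ctla2a at 7.18 and 4.60. EYFP was at 1.61 (SD 1.00) and 0.76 (SD 1.24). In the libraries rich in neutrophil-lineage-like cells the keratin-positive cells also carried neutrophil transcripts, with S100a8 at 5.72 in CJ002 against 0.94 in untagged cells, and at 4.49 in CJ004 against 0.151 in CJ003.

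**Figure D4:**
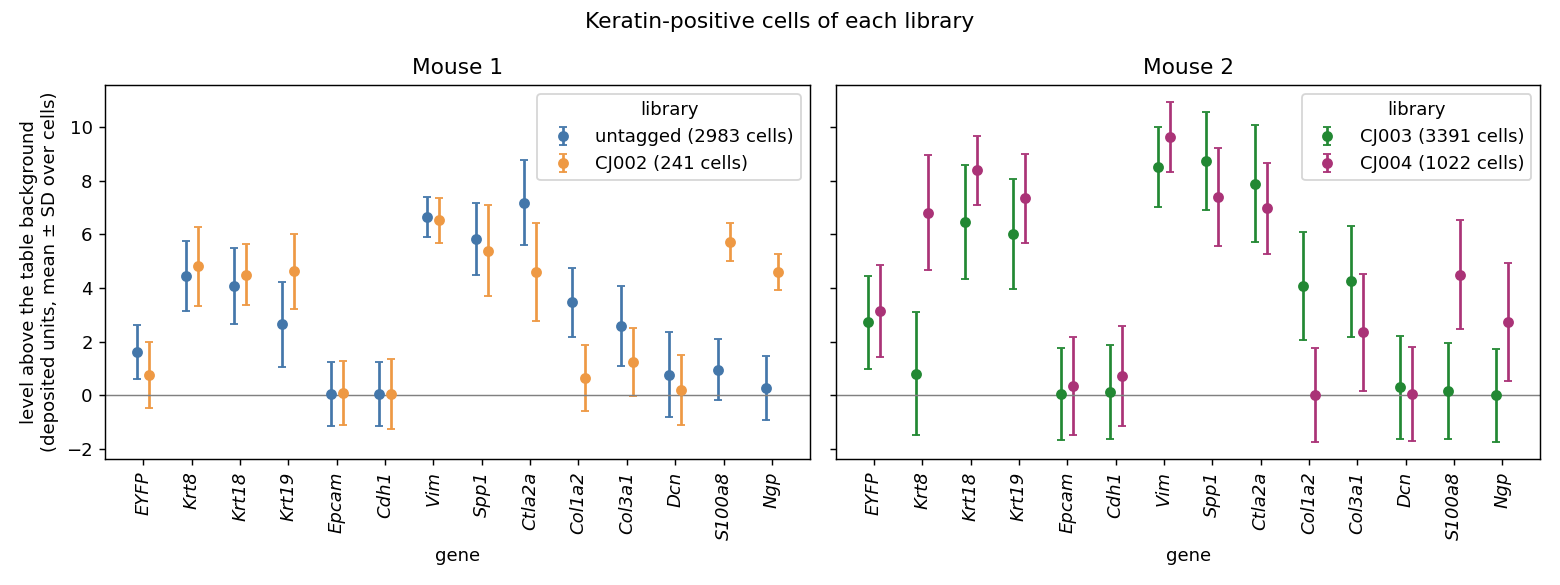
Level of 14 genes in keratin-positive cells of each library (y axis, deposited units above background), shown as mean and SD over cells, with mouse 1 left and mouse 2 right. Krt8 is at 0.801 in CJ003 and 6.80 in CJ004, and Col1a2 is at 3.46 and 4.07 in the untagged and CJ003 libraries against 0.65 and 0.014 in CJ002 and CJ004.

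Gene lists were set side by side between the libraries of a mouse within keratin-positive cells by the median difference of their members, untagged minus CJ002 and CJ003 minus CJ004. Most genes were lower in CJ003, and random lists matched to the RAS/MAPK and MYC-associated lists had medians of -0.316 and -0.362. In mouse 2 the RAS/MAPK list (-0.839, 8 of 21 genes higher by at least 1 unit in CJ004), the MYC-associated list (-0.841, 8 of 30), G2 and M phase (-0.767, 5 of 20), S phase (-0.76), p53 and senescence (-0.805) and the epithelial list (-0.501) were each below every random list. In mouse 1 the first 4 had small positive differences inside the limits, at 0.12 (percentile 96.9), 0.11 (86.7), 0.09 (84.6) and 0.11 (92.5), with p53 and senescence at 0.16 (99.05) and the epithelial list at -0.02 (12.7). Mesenchymal transition was at 0.205 in mouse 1 (percentile 99.9), with 3 of 16 genes higher in untagged cells, and at -0.062 in mouse 2 (99.8). Neutrophil maturation was at -0.488 in mouse 1 (below every random list) and -0.335 in mouse 2 (28.7). The luminal progenitor list was at -0.13 in mouse 1 (percentile 0.01) and -0.122 in mouse 2 (45.8). The 4 of its 12 genes higher by at least 1 unit in CJ002 were Krt7, Wfdc2 and the neutrophil transcripts Lcn2 (0.10 and 2.81) and Ltf (0.10 and 1.68). Also outside the limits were MHC class I at -0.22 (below every random list; H2-D1 was at 4.99 in neutrophil-lineage-like cells of mouse 1), NF-kB at -0.095 (0.02; its 2 genes higher in CJ002 were Lcn2 and Cxcl2, both abundant in neutrophil-lineage-like cells), androgen-regulated genes at -0.05 (1.97), oxidative phosphorylation at -0.04 (2.01) and interferon response at -0.04 (1.82) in mouse 1, and unfolded protein stress at -0.615 (1.88) and bone matrix at -0.003 (98.8) in mouse 2.

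Neutrophil-lineage-like cells were set apart in both mice by granule genes. S100a9 stood 8.95 above the mean of the other classes in mouse 1 and 7.98 in mouse 2, S100a8 8.53 and 7.34, Ngp (neutrophilic granule protein) 8.65 and 6.19, and Camp, the cathelicidin precursor, 7.74 and 4.72. Retnlg, a resistin-like protein of mature neutrophils (6.34 and 5.89), Lcn2 (level 8.41 and 7.39), BC100530 (4.78 and 4.53), Pglyrp1, a peptidoglycan receptor (5.82 and 4.29), Ifitm6 (5.36 and 3.79) and Mmp9 or gelatinase B (3.94 and 3.59) made up the rest. The neutrophil maturation list had medians of 1.68 and 2.22, above every random list, with 8 and 9 of 15 genes higher. Mesenchymal transition was below every random list at -0.85 and -1.83. The NF-kB and inflammatory list was at -0.15 in mouse 1 (percentile 8.89, inside the limits) and -0.133 in mouse 2 (percentile 99.5). The cell cycle lists were above random lists, with medians of 0.12 and -0.203 for S phase and 0.18 and -0.0423 for G2 and M phase, so in mouse 2 the class was not above the other classes. The G2 and M phase genes were confined to part of the class: in mouse 2 their median level was 2.97, 3.08 and 1.127 in clusters 9, 21 and 22 and at most 0.072 in clusters 1, 4 and 7, and in mouse 1 it was highest in cluster 6 (1.43).

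Clusters of the neutrophil lineage differed in granule genes. Cluster 11 of mouse 1 (142 cells) had Elane (neutrophil elastase), a primary granule gene of early precursors, at 6.80, and cluster 21 of mouse 2 (117 cells, all CJ004) had it at 10.2. Camp was highest in cluster 6 of mouse 1 (10.5) and cluster 9 of mouse 2 (11.5), which also carried the proliferation gene Mki67 at 2.15 and 5.14. Retnlg was highest in cluster 5 of mouse 1 (10.4) and cluster 1 of mouse 2 (9.78). Of the 321 neutrophil-lineage-like cells of CJ003, 300 fell in cluster 7, where the chemokine gene Cxcl2 was at 6.75, the cytokine gene Il1b at 5.30 and Ngp at 0.624. Over the class in mouse 2, Il1b was at 5.37 in CJ003 and 1.61 in CJ004, and Camp at 0.31 and 6.30.

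Monocyte-like cells were led by Chi3l3, a chitinase-like lectin, 4.49 and 6.26 above the other classes, followed by S100a8 (4.11 and 5.00), Lyz2 or lysozyme (4.07 and 4.80), Ly6c2, a surface marker of inflammatory monocytes (3.63 and 4.77), and S100a9 (3.40 and 3.59). Lyz1 (3.82 and 3.10), F13a1, a coagulation factor subunit (2.96 and 4.82), Plac8 (2.90 and 3.42), Ms4a6c (2.80 and 4.75) and Hopx (2.76 and 4.27) completed the list. Most of these cells were of CJ002 or CJ004. Keratin-positive cells of CJ002 had S100a8 at 5.72, S100a9 at 5.74, Plac8 at 3.24 and Chi3l3 at 2.06. Monocyte-like cells of mouse 1 had them at 8.02, 7.06, 4.76 and 6.45. For these 4 genes the lead over the pooled classes may therefore hold a difference between libraries. MHC class I presentation was above random in both mice (0.22 and 0.749, percentiles 99.94 and 99.72), as was G2 and M phase (0.21 and 0.891, above every random list). In mouse 2 the latter came from cluster 14 (213 cells, median level 3.52), which also carried the granulocyte precursor genes Elane (5.22) and Mpo (4.30), while cluster 12 (347 cells) was at 0.101. Hypoxia and glycolysis was below random, at -0.53 (percentile 0) and -0.298 (percentile 0.01).

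Macrophage-like cells were led by Apoe or apolipoprotein E, 4.85 and 6.06 above the other classes, and by the complement genes C1qb (4.27 and 5.64), C1qa (4.00 and 5.63) and C1qc (3.84 and 4.86). Antigen presentation genes followed, with the invariant chain Cd74 (4.12 and 4.11), H2-Ab1 (2.80 and 3.00), H2-Aa (2.80 and 3.15) and the protease Ctss (level 4.46 and 5.94), as did the survival gene Bcl2a1b (2.91 and 3.46) and Arg1 or arginase 1 (2.79 and 4.46). MHC class II presentation had medians of 2.498 and 2.79 with 5 of 7 genes higher in both mice, and the macrophage alternative list 0.55 and 0.872 with 4 and 7 of 16 higher. Both lists and the NF-kB and inflammatory list (0.81 and 0.188) were above every random list. The macrophage alternative list holds C1qa and Mrc1, which are among the markers used to name the class.

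Fibroblast-like cells, 39 in mouse 1 and 29 in mouse 2, were led by matrix genes. Col3a1 stood 6.58 and 6.69 above the other classes, Sparc (osteonectin) 6.47 and 7.59, Bgn (biglycan) 6.37 and 6.60, Igfbp7 5.90 and 6.68, Col1a1 5.94 and 5.85, and Col1a2 5.63 and 5.97. Dcn (decorin, 5.15 and 5.47), Mfap5 (4.97 and 4.89), Serping1, the C1 inhibitor (4.48 and 5.08), and Mgp (4.27 and 5.24) followed. The mesenchymal transition list had medians of 0.49 and 1.52 (percentiles 99.9 and 100), with 5 and 12 of 16 genes higher, and G2 and M phase was below every random list at -0.31 and -0.516.

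Keratin-positive cells of the 2 mice were also compared by the rank of each gene among 17720 genes of its own table, without a test, and genes with a level of at least 2 in either mouse are named. The largest shifts to a higher rank in mouse 2 were in Plaa (a rank difference of 63.8 percentile points), Nrn1 or neuritin (percentile 46.9 in mouse 1 and 91.4 in mouse 2), Rbp4, a retinol carrier (56.0 and 87.2), Zcchc11 (57.3 and 86.9) and Slc38a1, an amino acid transporter (59.4 and 87.8). Plac8, Csnk2a2, Cxcl15, Gpr64 and Brd1 came next, with rank differences of 27.8, 27.0, 25.9, 25.2 and 23.5. Genes of higher rank in mouse 1 were Crabp2, a retinoic acid carrier (95.9 and 53.9), Wdr89 (95.9 and 69.0), Krt8 (99.2 and 87.2) and Stmn1 or stathmin (95.3 and 83.4). Oaz2-ps, Cdk2ap2, Cyr61, Slc48a1, Nfkbia and Nr4a1 followed, with rank differences of -8.87, -8.62, -8.55, -8.21, -7.61 and -7.11. In mouse 2 Krt8 was at 0.801 in CJ003, which held most of these cells, and 6.80 in CJ004. A difference in rank between separately normalized tables is not a measured difference in expression.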

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

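Of the alternatives below, the 10 principal components, the median over cells, the log2 of the mean, the keratin-positive clusters led by another list left out and the single libraries were chosen after the data were seen. The order of keratin-positive and neutrophil-lineage-like shares within a mouse held under the 4 alternatives that gave shares (resolutions, doublets left out, 10 components). With 10 principal components keratin-positive cells were 95.8% of the untagged library and 81.9% of CJ003, and neutrophil-lineage-like cells 76.5% of CJ002. With possible doublets left out, keratin-positive cells were 95.6, 17.9, 78.9 and 24.4% of the untagged, CJ002, CJ003 and CJ004 libraries, and neutrophil-lineage-like cells 0.224, 70.4, 10.2 and 58.5%. Neutrophil-lineage-like cells were 56.5% of CJ004 at resolution 0.5 and 56.6% at 2.0, where keratin-positive cells were 85.7% of CJ003 and 24.3% of CJ004. The luminal progenitor median turned positive in mouse 1 with possible doublets left out (0.046) and in the untagged library alone (0.055), and in mouse 2 at resolution 0.5 (0.038) and 2.0 (0.067), with 10 components (0.074), doublets left out (0.073), the median over cells (0.012), clusters led by another list left out (0.017), and CJ003 (0.077) or CJ004 (0.088) alone. In mouse 1 it stayed negative but inside the limits at resolution 2.0, with 10 components, the log2 of the mean, the median over cells, clusters led by another list left out and CJ002 alone (percentiles 2.54 to 5.49). The unfolded protein median of mouse 1 turned positive with doublets left out (0.003), the median over cells (0.034), and the untagged library (0.046) or CJ002 (0.194) alone. Neutrophil maturation was at -2.04 in mouse 1 with the log2 of the mean, and in mouse 2 at -2.21 with 10 components and -0.89 in CJ003 alone. In mouse 2 the MYC-associated and RAS/MAPK medians were 1.72 and 1.71 with clusters led by another list left out and 2.05 and 2.16 in CJ004 alone, where MHC class I was at 0.171 and MHC class II at -1.29. Of the 10 lists in 2 mice, 18 of 20 calls held with 10 components, doublets left out or resolution 2.0, and 19 of 20 at resolution 0.5, with the median over cells or with clusters led by another list left out. The NF-kB, macrophage alternative, neutrophil maturation and both MHC lists kept their side of the limits throughout. Within single libraries 7 of 10 held in the untagged library, 6 in CJ002, 5 in CJ003 and 9 in CJ004. The cause was not tested, and classes with under 10 cells also drop out of the reference there (monocyte-like in the untagged library, fibroblast-like in CJ002 and CJ004). Levels in keratin-positive cells were followed per library for EYFP, Krt8, Krt18, Krt19, Vim, Col1a2, Col3a1, Epcam and S100a8. They moved in 9 comparisons and not in 225. Of the 9, 5 came with clusters led by another list left out, 3 with possible doublets left out and 1 with the median over cells. For lists not called in both mice, 9 medians also moved. No paired analysis was possible because the columns are tied to no sample. The planned filters, pseudocounts, scalings, cell weights, mouse block, correlation settings and leave-one-out were not run, since they need counts or a fit between groups. Depth is unknown, so what it limits was not tested. The fibroblast-like class was not recovered in mouse 2 at either other resolution, nor in either mouse with 10 components, and at resolution 0.5 mouse 2 had no macrophage-like class either.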

Other observations

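All the tests in this part were chosen after the results were seen. A cluster of 30 cells in mouse 2, all of CJ003, differed from the keratin-positive class by its adhesion genes. Epcam was at 7.25 there against 0.118 in keratin-positive cells, and Krt8 at 7.10. Its leading genes were Clu (clusterin) at 9.56, Akr1b7, an aldo-keto reductase, at 6.46, Spink8, a protease inhibitor gene, at 5.52 and Crisp1, a cysteine-rich secretory protein gene, at 5.49. EYFP was at 1.03 in these cells. No such cell was found among the 4529 of CJ004, which allows a share of up to 0.081% by the exact interval.

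Proliferation set some keratin-positive clusters apart. In mouse 2 Mki67 was at 3.83 in cluster 10 (370 cells, 361 of CJ004), 4.31 in cluster 11 (369 cells, 368 of CJ003), 3.15 in cluster 25 and 4.13 in cluster 29, against 0.967 over the class. In mouse 1 its highest levels were 1.04 in cluster 2 (782 cells) and 0.97 in cluster 15 (60 cells). Cluster 13 of mouse 1 (89 cells) had the glucose transporter Slc2a1 at 2.67, Adm (adrenomedullin) at 2.15 and Bnip3, a hypoxia-induced mitophagy gene, at 2.81, against 1.11, 0.31 and 1.61 over the class. An unnamed cluster of mouse 2 (174 cells) was led by Cd74, MHC class II genes, Cd79a, a B cell receptor component, and Il7r, the IL-7 receptor. Among erythroid-like cells, cluster 23 (64 cells, all CJ004) had Mki67 at 5.55 and cluster 24 (61 cells) had Hbb-b2, a beta globin gene, at 4.41.

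Keratin-positive cells carried neutrophil transcripts in CJ002 and CJ004, as given above. S100a8 was at a level of 2 or more in 100% of the keratin-positive cells of CJ002 (241 of 241) and 94.7% of those of CJ004 (968 of 1022), which argues against doublets, since these would put it in a minority of cells. In CJ002 the level differences of S100a8, S100a9, Retnlg, Ngp and Camp between keratin-positive cells and macrophage-like or unnamed cells had an SD over genes of at most 0.212. S100a8 was at 5.72 in keratin-positive and 5.71 in the 11 macrophage-like cells, so free RNA of neutrophil-lineage cells is a candidate source. Monocyte-like cells, whose leading genes include S100a8 and S100a9, were not compared. Their cluster in mouse 1 (201 of 202 cells of CJ002) had S100a8 at 8.02 and Ngp at 4.31. In CJ004 the SD against macrophage-like, erythroid-like and unnamed cells was at most 0.446. However, S100a8 was at 4.49 in keratin-positive, 4.34 in macrophage-like, 3.29 in erythroid-like and 2.48 in unnamed cells. The mean difference over the 5 genes reached 1.76, beyond the bound of 1 set after that value was seen, so the source in CJ004 stays open. Monocyte-like cells were again not compared, and had S100a8 at 8.93 over the class in mouse 2. The libraries are tied to no group, so no biological explanation was tested.

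Krt8 was low in keratin-positive cells of CJ003 while Krt18 and Krt19 were high. Krt8 was at 7.10 in the Epcam-positive cells of the same library, which argues against a loss of its reads from the whole library. Over 112 genes as high as Krt8 in CJ004, the median difference, CJ003 minus CJ004, was -0.547, and none was under 2 in CJ003, which argues against depth or scaling as the whole cause. In cluster 13, filled by both libraries, Krt8 was at 0.457 in 132 cells of CJ003 and 4.28 in 91 of CJ004, a difference of -3.82. Cluster membership therefore does not account for it within this cluster. Cluster 13 had the lowest mean level over genes (0.808) of the keratin-positive clusters of mouse 2, and cells of different populations could group there. Whether the libraries hold different keratin-positive populations cannot be told from it. An effect of the authors' processing on this gene in these cells was not tested, and no biological explanation was tested.

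In keratin-positive cells of the untagged library and CJ003 the collagen gene Col1a2 was at 3 or more in 67.0% and 79.5% of cells against 4.72% and 3.49% of macrophage-like cells of the same libraries, and its level was higher than in macrophage-like cells by 2.87 and 3.84, which argues against free RNA. Over all keratin-positive cells Dcn was at 0.76 and 0.294, against 5.61 and 5.90 in fibroblast-like cells. The gap between Dcn and Col1a2 minus the same gap in fibroblast-like cells was -1.73 in the untagged library, between the bounds of -1 and -2, so by Dcn alone doublets with fibroblast-like cells cannot be told apart from other sources there, and -2.82 in CJ003. In CJ003 the Dcn gap argues against such doublets as the source over the class as a whole. Bgn was at 0.16 and 0.218 against 6.54 and 6.59 in fibroblast-like cells, with like gaps of -3.26 and -3.58. Bgn was chosen after its level was known, so these gaps cannot decide, and doublets stay open in the untagged library. All gaps are over the whole class and do not exclude doublets in a part of it. In clusters 1 and 7 of mouse 1 the top genes held the fibroblast markers Col1a2 or Col1a2 and Col3a1, and no luminal marker. What lies behind the transcripts stays open, since no biological explanation was tested.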
